A study of Petromyzon marinus with 2 samples.

How the data were processed

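Polyadenylated RNA of 2 pools of sea lamprey oocytes was sequenced as paired-end Illumina libraries, per the labels' protocols. Reads were aligned with HISAT2 2.2.1 and genes quantified with StringTie 2.2.3, per the submitters' processing notes, and the series' design text names median of ratios normalization in R. The genome build is not given in the sources used here. Coordinates are those of the gene annotation the authors deposited, 1-based, on its own sequence names.

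The deposited expression table is called FPKM by the authors, but its values are a signal of another kind: gene counts divided by 1 size factor per library and not by gene length. In each library 100% of the values above 0 were whole multiples of 1 step (within 0.01 of a whole number), the same for genes of every length. The step was 1.07 in replicate 1 and 0.763 in replicate 2. The count units recovered in this way appear to be derived from coverage. The most frequent value among low ones was 4 units (351 genes in replicate 1 and 357 in replicate 2), so 4 units were taken as 1 read pair. This conversion is an inference from the values. FPKM was computed here as units per kilobase of summed exons, overlaps merged, scaled to the library's total units as FPKM is, and replaces the deposited scale throughout, so that the FPKM thresholds fixed beforehand could be used as written. A value of 0 can be a failed estimate, since some ribosomal protein genes are also at 0, and such genes are said to be listed at 0. The kit's strandedness and its use in counting are not given in the sources used here. With 1 group of libraries no count model had a comparison to test, so none was run on the recovered counts. The table also has 1 column of a library of another series, which was not used in any step.

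Both libraries form 1 group, oocyte, with the replicate numbers of the labels. A gene model was germline-specific where its deposited identifier carries the germline mark, and all other models were taken as somatic and are called unmarked. A model was detected at 1 FPKM or more in both libraries. Shares carry exact Clopper-Pearson intervals at the 95% level over gene models. Classes were compared with Fisher's exact test, families with an exact binomial test, and medians by their percentile among 10000 seeded random sets, matched on 10 exon-length deciles for the classes. A pseudocount of 1 was added before logs. Families are sets of models that share a symbol across both classes. The 18 gene lists were fixed before the data were examined, and symbols matched with or without a copy suffix. With 1 value per symbol, the median over the models of a symbol was used, and random lists were drawn from symbols. Floors are 3 read pairs per library. The ribosomal RNA cluster holds the models within 10 kilobases of an annotated subunit rRNA. That distance was chosen after seeing the data, and 1 further model that overlaps the cluster is left out in a separate alternative.

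Named genes follow a rule fixed before the data were examined: the 20 highest named germline-specific models, the 10 highest models of all, the 3 highest of each list, 5 families at each end of the ratio, and the 5 named genes with the largest library differences each way. The last part did not name a level, and the mean of at least 5 FPKM of the size rule for library differences was applied to it after seeing the data. At most 2 unnamed models are given by identifier. Some genes that the rule names are not reported here. Alternatives were other FPKM thresholds (0.1 and 5), a pseudocount of 0.1, no filter on low values, models with a symbol, exons of at least 500 bases, median of ratios scaling, each library alone, other family and matching rules, and exclusions added after seeing the data.

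Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. The step was recovered in each simulated library, and 100% of the simulated counts of 25255 genes were recovered exactly. Fisher's test called 3% of 100 null classes and 100% of 100 classes lowered 8-fold. The family test called 3% of 200 null sets of 55 families. Simulated classes were random genes with independent counts, and simulated families were independent ratios. These rates therefore do not cover copies that share reads or the choice of families by detection.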

Results

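Messenger RNA was measured in oocytes of the sea lamprey (Petromyzon marinus), a jawless vertebrate that discards part of its genome from somatic cells early in development, so that some chromosomes are carried by the germline alone. The series holds 1 group of 2 libraries, replicate 1 and replicate 2, each made from a separate pool of oocytes. The title sets the question as the role of the germline-specific chromosomes in oocytes. The comparisons are therefore between classes of gene models inside each library, and no comparison between groups of samples was possible. The labels do not say whether the pools came from separate animals, so the spread between the libraries may be technical. Recovered totals were 82562259 count units in replicate 1 and 110706420 units in replicate 2, with about 4 units to a read pair. A level of 3 read pairs corresponded to 0.106 FPKM in replicate 1 and 0.0792 FPKM in replicate 2 for a gene model of the median germline-specific exon length, 1368 bases. Intervals over gene models treat each model as an independent draw, and these floors cover counting error only. Neither covers differences between pools or animals. FPKM was computed here from the recovered units and exon lengths, and values are means ± SD of the 2 libraries unless a library is named.

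The named gene model with the highest level outside the germline-specific class was NT5DC2-domain (PM19354, chromosome 46, 5728686 to 5755325), annotated as a nucleotidase-domain protein, at 2742 ± 29.0 FPKM (SD, n = 2). ODC1 (PM13777, chromosome 27, 6586636 to 6593841), ornithine decarboxylase of polyamine synthesis, stood at 1915 ± 8.33 FPKM (SD, n = 2). NASP, a histone chaperone, followed at 1376 ± 67.1 FPKM, and KPNA2, a nuclear import receptor, at 1331 ± 21.7 FPKM (SD, n = 2). The cyclins CCNB2 and CCNA2 reached 1233 ± 77.2 and 1025 ± 4.22 FPKM, and the mitotic kinase PLK1 1187 ± 204 FPKM (SD, n = 2). The membrane protein gene MAL stood at 1213 ± 20.1 FPKM, and GBP7, a guanylate-binding protein, at 1167 ± 670.5 FPKM. ODC1, NASP, KPNA2 and MAL were chosen after their values were seen, because 8 of the 10 highest gene models of all belonged to, or overlapped, the ribosomal RNA cluster described with the germline-specific genes. The remaining member of those 10 was an unnamed model on chromosome 40 (3734409 to 3740984) at 3048 ± 390 FPKM.

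The libraries were close to each other. Across 10156 gene models with at least 1 FPKM in either library, Pearson's r of log2(FPKM + 1) was 0.995 and Spearman's rho 0.992, across genes, which are not independent replicates. The SD per library of the log2 value was 0.13. At least 1 FPKM in both libraries, the level called detected here, was reached by 9725 of 25255 gene models (38.5%).

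**Figure D1:**
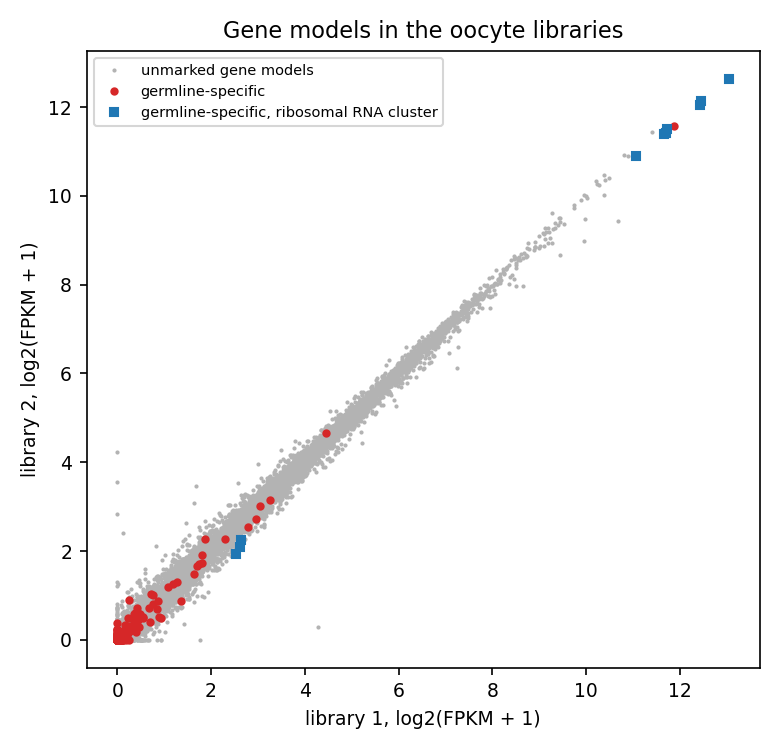
Expression of 25255 gene models in replicate 1 (x axis) and replicate 2 (y axis), both as log2(FPKM + 1). Grey points are unmarked gene models, red points germline-specific models and blue squares the 10 models of the ribosomal RNA cluster, 7 of which are among the 10 highest gene models.

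Few germline-specific gene models were detected. The annotation marks 770 gene models as germline-specific, 389 of them with a gene symbol, and 26 were detected in both libraries (3.38%, exact 95% interval 2.22 to 4.91%). Of the 24485 unmarked models, taken here as somatic, 9699 were detected (39.6%, exact interval 39.0 to 40.2%). The odds ratio was 0.0533 (Fisher's exact test, two-sided, p = 8.5e-123), with gene models as the units, which are not independent replicates. Replicate 1 alone gave 27 detected germline-specific models and replicate 2 alone 28. Some symbols are carried by many models. Counted by symbol, 6 of 76 symbols shared with unmarked models had a detected germline-specific model. Of 27 symbols on germline-specific models only, 2 had a detected model. A further 540 germline-specific models (70.1%) were listed at 0 in both libraries, against 6754 unmarked models (27.6%). Germline-specific models were also shorter, with a median exon length of 1368 bases against 2638.

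**Figure D2:**
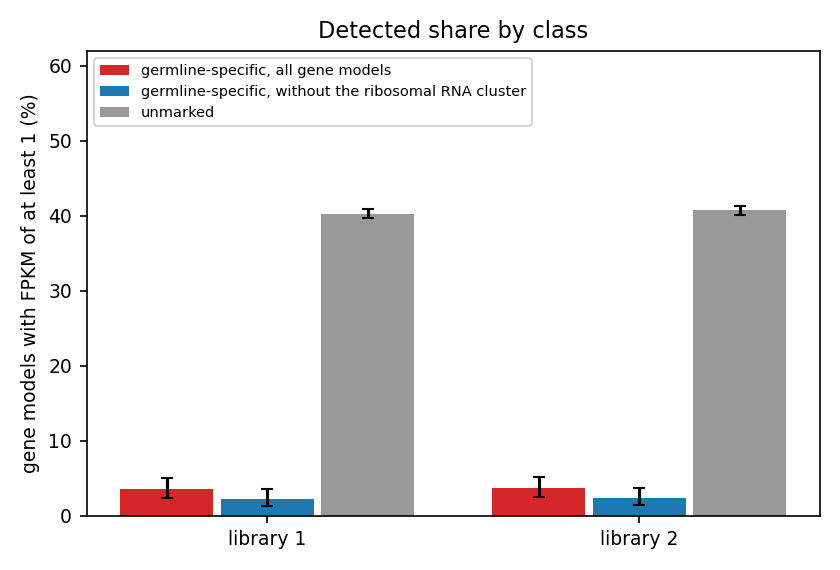
Share of gene models with at least 1 FPKM (y axis, percent) in each library, with exact 95% intervals. Red bars are all germline-specific models, blue bars those outside the ribosomal RNA cluster and grey bars unmarked models, whose share was 40.3% in replicate 1 and 40.7% in replicate 2.

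Of the 26 detected models, 10 lay in a ribosomal RNA cluster on unplaced scaffold 120 and 1 more overlapped it. The highest was a small-subunit rRNA model on part C of the scaffold (10277 to 12100) at 7423 ± 1474 FPKM, followed by an unnamed model across it (6704 to 22447) at 5049 ± 716 FPKM (SD, n = 2). A large-subunit model on part B (209947 to 214813) reached 3130 ± 331 FPKM. All 3 annotated subunit rRNA models carry the germline mark and 0 unmarked models do so, so the table cannot place such reads on a somatic copy. With the cluster, germline-specific models held 12.9% of all FPKM in replicate 1 and 10.6% in replicate 2. Without it the share was 1.57% and 1.29%, and without the overlapping model as well it was 0.0388% and 0.0396%. These exclusions were chosen after seeing the data. The unnamed model across the small-subunit model lies on the opposite strand. Strandedness in counting is not given, so the same reads may be counted on both. Because polyadenylated RNA was sequenced, these shares do not measure the level of ribosomal RNA in the oocytes.

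The detected germline-specific models with a symbol numbered 12. HSP90AB1, a heat shock chaperone, had 3 germline-specific models, all detected, of which the highest (PM00255, unplaced scaffold 678, 66251 to 70225) stood at 8.26 ± 0.487 FPKM (SD, n = 2). The others reached 6.15 ± 0.822 FPKM (PM00922) and 3.25 ± 0.833 FPKM (PM03010), and the neighbouring HSP90AA1 (PM00254) 5.35 ± 0.793 FPKM. CDC20, an activator of the anaphase-promoting complex, was detected from 2 of its 3 models. These lay on unlocalised sequence 2 of chromosome 81 (PM03723, 345400 to 356108), at 7.17 ± 0.0976 FPKM, and on unlocalised sequence 1 of chromosome 81 (PM00614, 36561 to 47962), at 2.21 ± 0.0268 FPKM (SD, n = 2). No unmarked model carries the symbol CDC20 or HSP90AB1, but unmarked copies under other or missing names were not searched for. Unmarked models of HSP90AA1 summed to 74.1 ± 3.01 FPKM. NDUFAF3, an assembly factor of respiratory complex I, stood at 3.86 ± 0.0274 FPKM, and CEP41, a centrosomal protein, at 2.30 ± 0.0571 FPKM (SD, n = 2). BIRC3, an inhibitor-of-apoptosis gene, was detected from 2 models at 2.63 ± 0.217 and 2.41 ± 0.125 FPKM. The ephrin receptor EPHA5 reached 1.43 ± 0.0298 FPKM and NAIP, of the BIRC3 family, 1.33 ± 0.0702 FPKM. MAD2L1BP, which binds the spindle checkpoint protein MAD2, stayed below 1 FPKM in its highest model, at 0.835 ± 0.0110 FPKM. VGLL2 (0.707), CTNND2 (0.642), BCL11A (0.5003), LRRC8C (0.476) and LSM14A (0.453) were lower still in mean FPKM. The highest germline-specific model outside the cluster and its overlap had no name (PM03720, unlocalised sequence 2 of chromosome 81, 292759 to 313196) and reached 22.7 ± 2.36 FPKM (SD, n = 2). Where these genes have close copies, reads could not be assigned to one copy from the files.

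Among detected models the germline-specific class also had the lower median. The median log2(mean FPKM + 1) was 2.56 for 26 germline-specific models and 2.99 for 9699 unmarked ones, a difference of -0.43, with -0.25 in replicate 1 and -0.62 in replicate 2. The germline-specific median lay at percentile 12.4 of 10000 random unmarked sets matched on exon length. That percentile depended on the models included. It was 2.09 for 12 detected models with a symbol and 23.6 for 21 with exons of at least 500 bases. Detection called in replicate 1 alone gave 25.4 (27 models). With no filter on low values it was 0 for all 770 models, where the difference was -0.39. As 70.1% of germline-specific models were listed at 0 in both libraries, that last value restates how few were detected. Outside the ribosomal RNA cluster, an alternative chosen after seeing the data, 16 models gave a difference of -1.02 at percentile 1.86.

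By sequence, 71 germline-specific models lay on chromosome 81 and its unlocalised sequences, and 4 were detected (5.63%, exact 95% interval 1.56 to 13.8%). On the unplaced scaffolds 22 of 698 were detected (3.15%, exact interval 1.99 to 4.73%), and without the ribosomal RNA cluster 12 of 688 (1.74%, exact interval 0.904 to 3.03%). The only other marked model, VGLL2 (PM20470), lay on chromosome 51 (6401804 to 6481172) and was not detected. Of 25 sequences with at least 10 germline-specific models, 9 had a detected model. Unlocalised sequence 2 of chromosome 81 had 3 of 19 (15.8%, exact interval 3.38 to 39.6%), whereas chromosome 81 itself had 0 of 34, which allows up to 10.3%. Parts B and C of scaffold 120, which hold the ribosomal RNA cluster, had 7 of 14 and 4 of 12.

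Somatic copies were higher than germline-specific copies in nearly all shared gene families. A symbol was carried by both classes in 76 families, and 55 of them had a detected model. The unmarked side was higher in both libraries in 54 of these 55 (98.2%, exact 95% interval 90.3 to 100.0%; exact binomial test against an even split, two-sided, p = 3.1e-15, with families as units that are not independent replicates). The median log2((germline + 1)/(unmarked + 1)) was -3.57. By this ratio, with its pseudocount of 1, the widest gap was in CDH2, the adhesion molecule N-cadherin, with 0.0782 ± 0.00824 FPKM summed over 16 germline-specific models and 434 ± 44.2 FPKM over 14 unmarked ones (log2 ratio -8.65). LSM14A, an RNA-granule protein, stood at 0.463 against 407 FPKM (-8.13). It ranked 2 with this pseudocount and 8 with a pseudocount of 0.1, whereas CDH2 ranked 1 with both. The transcription factor MYCN was listed at 0 from its germline-specific models in both libraries and reached 167 ± 3.96 FPKM from unmarked ones. The phosphatase PPM1D stood at 155 ± 2.35 FPKM and the splicing factor HNRNPL at 165 ± 6.39 FPKM on the unmarked side, with germline-specific sides at or below 0.0849 FPKM. NAIP was the exception, with 1.33 FPKM from the germline-specific side and 0.00453 FPKM from the unmarked side. The germline-specific value came from 1 model of 509 exon bases (PM03725), with 54 units in replicate 1 and 78 in replicate 2. The next smallest gaps were in MAD2L1BP (2.65 against 3.23 FPKM), NDUFAF3 (3.86 against 8.07), HYKK (0.999 against 2.73) and VGLL2 (0.707 against 2.23). Of the 55 families, 54 had a detected unmarked model, 6 a detected germline-specific one and 5 both. The family count therefore largely restates the lower detected share of germline-specific models. Reads of close copies could not be assigned to one copy, and germline-specific reads counted on unmarked copies were not tested. Families were formed by shared symbol, and the authors' own paralog groups were not used here.

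**Figure D3:**
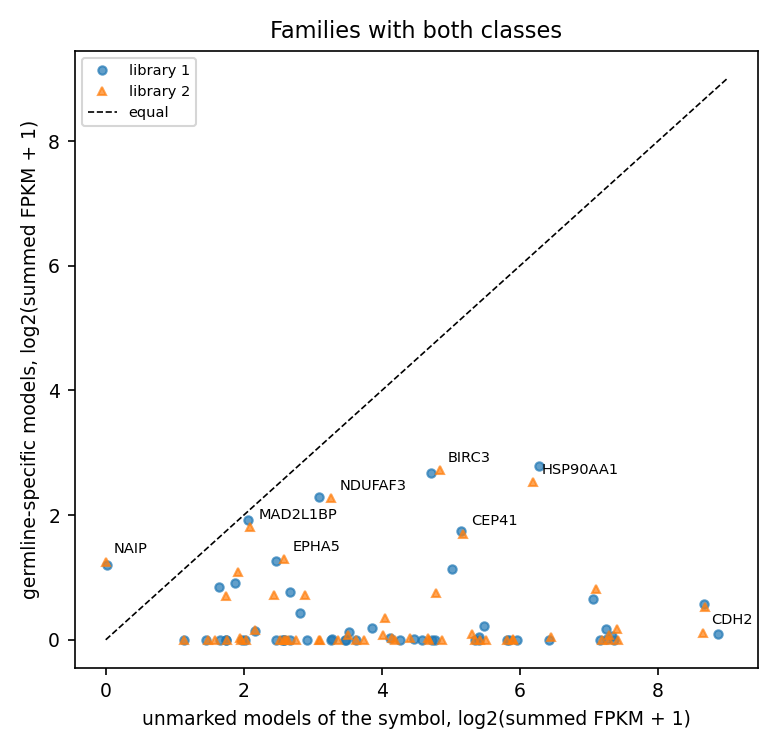
Summed FPKM of germline-specific models (y axis) against unmarked models (x axis) of the same symbol, both as log2(summed FPKM + 1), for 55 families with a detected model. Circles are replicate 1, triangles replicate 2 and the dashed line marks equal levels, with NAIP alone above it.

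Genes of the cell cycle and copies of a few egg envelope genes were broadly detected. Levels of all lists are those of polyadenylated RNA, and RNA without such a tail was not measured. Percentiles count each model of a list, and percentiles with 1 value per symbol are an alternative chosen after seeing the data. Of 45 models of cell cycle and meiotic maturation genes, 39 were detected with a median of 25.03 FPKM, at percentile 100 of 10000 random lists (also with 1 value per symbol), led by CCNB2, PLK1 and CCNA2. The 26 egg envelope models carry only 5 symbols, and 24 were detected with a median of 13.6 FPKM (percentile 99.99, and 93.7 with 1 value per symbol), with the envelope glycoprotein gene ZP3 at 152 ± 13.9 and 50.1 ± 5.22 FPKM and the cortical granule protease ASTL at 73.8 ± 1.39 FPKM (SD, n = 2). Cohesin and kinetochore genes were detected in 25 of 30 models (median 9.46 FPKM, percentile 99.99), with NDC80 at 173 ± 4.06, CENPC at 101.2 ± 7.89 and CENPN at 75.9 ± 6.05 FPKM. Translation control genes were detected in 31 of 41 models (median 5.78 FPKM, percentile 99.8). Among them CPEB1, which controls cytoplasmic polyadenylation of maternal mRNA, reached 467 ± 13.1 FPKM, and 2 unmarked LSM14A models reached 277 ± 0.661 and 67.5 ± 4.54 FPKM. Polycomb and heterochromatin genes were detected in 31 of 42 models (median 3.63 FPKM, percentile 98.1), with CBX1 at 186 ± 11.7, HELLS at 112 ± 3.39 and DNMT1 at 91.0 ± 4.57 FPKM (SD, n = 2). Nuclear-encoded respiratory chain genes were detected in 30 of 45 models (median 3.03 FPKM, percentile 96.6, 93.5 in replicate 1 alone and 77.1 with 1 value per symbol), led by COX7A2 at 297 ± 37.5, COX6A1 at 134 ± 9.35 and NDUFA4 at 70.7 ± 6.998 FPKM.

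Oocyte and germ plasm genes were mostly detected, but their shares were not set apart from that of other named genes. The exact intervals were 44.0 to 89.7% for oocyte maternal factors and 48.8 to 90.9% for germ plasm and piRNA genes. Both intervals include the 51.4% detected among all unmarked models with a symbol. Oocyte maternal factors were detected in 12 of 17 models (median 3.32 FPKM, percentile 89.3, and 97.7 with 1 value per symbol), with ZAR1 at 221 ± 6.32, FBXO43 at 148 ± 1.37 and TRIM71 at 90.3 ± 0.0509 FPKM (SD, n = 2). The 8.82 FPKM median over symbols equals the mean of MOS, which was listed at 0 in replicate 1. The percentile of 97.7 was not computed for each library alone. Germ plasm and piRNA genes were detected in 14 of 19 models (median 3.48 FPKM, percentile 91.5, and 80.1 with 1 value per symbol), with WDR77 at 65.1 ± 3.50035 and PUM2 at 29.4 ± 1.23 FPKM. Cytosolic ribosomal protein genes were detected in 42 of 99 models (median 0.833 FPKM, percentile 27.9, and 2.13 with 1 value per symbol), with RPL24 at 105 ± 8.27 and RPS28 at 39.5 ± 3.499 FPKM. The highest match of that list, RPS19BP1 at 183 ± 21.1 FPKM, is a binding partner of a ribosomal protein and not one itself, and 14 of the 99 models were listed at 0 in both libraries.

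Meiotic prophase and recombination genes had 12 of 48 models detected and a median of 0.0428 FPKM (percentile 0), with the repair gene EXO1 at 40.4 ± 3.14 and TRIP13 at 11.6 ± 0.620 FPKM (SD, n = 2). The Wnt and cadherin list had 21 of 94 detected (median 0.0187 FPKM, percentile 0), although CTNNB1 reached 599 ± 29.1, the CDH2 model PM13050 229 ± 24.7 and FZD7 193 ± 20.6 FPKM. Both lists hold many germline-specific models, 18 and 28, of which 0 were detected. Among unmarked models alone, an alternative chosen after seeing the data, 12 of 30 meiotic prophase models were detected (40.0%, exact 95% interval 22.7 to 59.4%), with a median of 0.365 FPKM at percentile 7.18 of random unmarked lists. The detected share of unmarked models with a symbol was 51.4%. The unmarked Wnt and cadherin models had 21 of 66 detected and a median of 0.107 FPKM (percentile 0.03). With 1 value per symbol, germline-specific models included, the meiotic prophase list lay at percentile 0.08 (median 0.169 FPKM). The Wnt and cadherin list then lay at 0.02. Over all lists, 60 germline-specific models carried a member's symbol, and the CDC20 pair were the only ones detected. The other members were CCNB1IP1, CDH2, HFM1, LSM14A, LSM14B, MSH4, RPL37A, WNT5A, WNT5B, WNT7A, WNT7B and YTHDC2, the highest of them LSM14A at 0.453 FPKM.

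Markers of other cells were low as lists, with single genes at high levels. Follicle cell and steroidogenic genes had 2 of 25 models detected (percentile 0.06), with FST at 9.27 ± 0.0361, NR5A2 at 1.24 ± 0.461 and CYP11A1 at 1.16 ± 0.141 FPKM. Erythroid genes had 2 of 22 (percentile 0.02), with EPB41 at 60.4 ± 0.0727, TFRC at 1.57 ± 0.426 and KLF1 at 0.0698 ± 0.0468 FPKM. Leukocyte genes had 2 of 14 (percentile 0.95). One of these, LCP1l at 57.2 ± 1.91 FPKM, is annotated as a digestive cysteine proteinase and matched the list by name alone, and CTSS models stood at 3.20 ± 1.13 and 0.181 ± 0.136 FPKM. Muscle genes had 4 of 34 (percentile 0), with DES at 88.8 ± 3.71 and 5.04 ± 0.138 FPKM and MYL9 at 67.6 ± 2.65 FPKM (SD, n = 2). Stroma and endothelium genes had 3 of 26 (percentile 0.9), with FN1 at 192 ± 3.03 and 2.42 ± 0.0591 FPKM and VWF at 1.15 ± 0.00260 FPKM. Sperm genes had 2 of 32 (percentile 2.2), both ODF2, at 5.31 ± 0.372 and 4.80 ± 0.113 FPKM, and ZPBP2 stood at 0.995 ± 0.09995 FPKM. Liver and yolk precursor genes had 0 of 17 (exact upper limit 19.5%, percentile 4.13), the highest being C3 at 0.635 ± 0.181 FPKM and PLG at 0.485 ± 0.0625 and 0.443 ± 0.0455 FPKM.

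**Figure D4:**
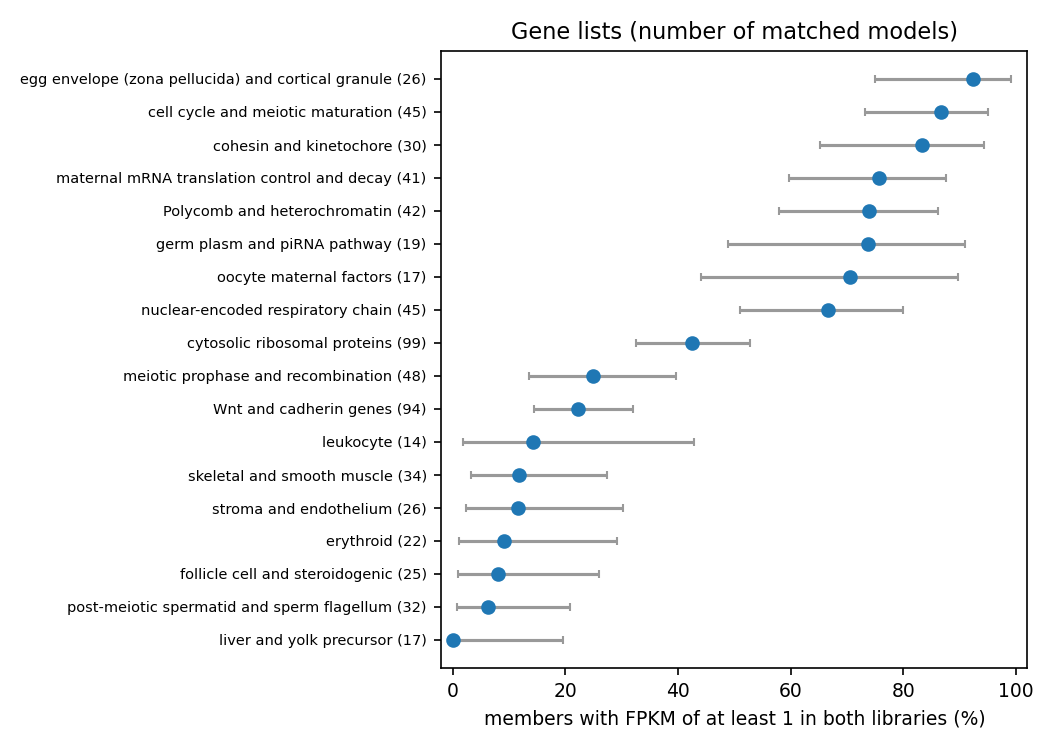
Share of matched gene models with at least 1 FPKM in both libraries (x axis, percent) for each gene list, with the number of matched models in brackets and exact 95% intervals as bars. Egg envelope and cell cycle genes are highest, at 92.3% and 86.7%, and liver and yolk precursor genes lowest, at 0%.

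Differences between the libraries were rare. Of 5711 gene models with a mean of at least 5 FPKM, 3 differed by at least 2 on the log2(FPKM + 1) scale, 2 of which are described here. MOS, the kinase that holds the egg in meiotic arrest (PM03915, chromosome 2, 9593901 to 9596309), was listed at 0 in replicate 1 and at 17.6 FPKM in replicate 2. The unnamed PM18081 (chromosome 41, 10595343 to 10595672) went the other way, from 18.6 to 0.219 FPKM. MOS and PM18081 overlap another gene model on the opposite strand. Smaller differences were seen in GBP7 (1641 FPKM in replicate 1 and 693 in replicate 2), CD82 (151 and 68.6), oscp1a (995 and 506), LSM7 (36.3 and 20.7) and CLDN3 (689 and 407). CSNK1E (2.19 and 10.0), gemin7 (7.06 and 14.4) and RPS25 (5.47 and 8.61) were higher in replicate 2. With 1 library on each side there was no test of these differences.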

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

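No paired analysis was possible because there is 1 group. The exclusions of the ribosomal RNA cluster, the protein-coding, exact-symbol, unmarked-list and count-unit settings, the ribosomal protein list without look-alike names, the lists with 1 value per symbol and the family comparison without families whose germline-specific side was at 0 in both libraries were chosen after seeing the data. The lower detected share of germline-specific models and the higher unmarked side of families kept direction and significance under every alternative run for them. The family result is not a separate finding, as it largely restates the detected share. Of the 55 families, 54 had a detected unmarked model and 6 a detected germline-specific one. Odds ratios ranged from 0.0301 (symbol only) to 0.0853 (0.1 FPKM). Either library alone gave 9888 to 9993 detected models. The library correlation moved to 0.990 with a pseudocount of 0.1 and to 0.998 with no filter. At 5 FPKM the detected models numbered 5572 and the detected list members 181, against 9725 and 295. The class difference of medians moved to -1.08 for models with a symbol, -1.02 without the cluster and -1.13 also without the model overlapping it, and, with detection called in a single library, was -0.68 in replicate 2 (28 models, percentile 4.4) and -0.28 in replicate 1 (27 models, percentile 25.4). Its percentile was 12.4 as reported, 2.09 with a symbol, 0 with no filter and 23.6 with exons of at least 500 bases. The share of FPKM moved from 11.7% to 0.0295% for models with a symbol, 0.0586% without the 100 highest models, 1.43% without the cluster, 0.0392% also without the model overlapping it, and 6.20% as a share of count units. So that share rests on the cluster. Sequences with a detected model numbered 18 at 0.1 FPKM, 4 at 5 FPKM, 4 of 7 with a symbol and 5 of 14 with exons of at least 500 bases, against 9. Detected germline-specific list members numbered 4 at 0.1 FPKM and 1 at 5 FPKM, against 2. Library differences numbered 5 at a mean of at least 1 FPKM, against 3. The lists at or above percentile 95 numbered 6, and 5 in replicate 1 alone or with 1 value per symbol, where oocyte maternal factors moved to 97.7, the egg envelope to 93.7, germ plasm to 80.1 and the respiratory chain to 77.1. The median of the oocyte maternal factors in that setting equals the mean of MOS, listed at 0 in replicate 1. The ribosomal protein list lay at percentile 27.9, at 56.5 with lists matched on exon length, at 22.6 without look-alike names and at 2.13 with 1 value per symbol, so its place depends on the setting. Fewer models pass a higher threshold or a subset by construction, and the cause of the other moves was not tested. The level of 3 read pairs lay at 0.106 and 0.0792 FPKM for the median germline-specific exon length, below the detection threshold of 1 FPKM, so depth limits statements on levels below these floors.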

Other observations

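All tests in this part were chosen after the result was seen. Of 13 protein-coding mitochondrial models 9 were detected, and the median of the 13 was 2.63 FPKM. MT-CO1 stood at 6.30 ± 0.501 FPKM and MT-ND1 at 4.73 ± 0.912 FPKM (SD, n = 2). The 13 models together held 0.00295% of the units in replicate 1 and 0.00369% in replicate 2.

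The 3 subunit ribosomal RNA models, which carry the germline mark, were among the 10 highest gene models. A candidate explanation is reads of somatic ribosomal RNA placed on the germline-marked models for want of an unmarked subunit model. The annotation holds 0 unmarked subunit rRNA models, and all 3 such models carry the mark. For the smaller 5.8S rRNA, the 3 marked models held 197 and 171 units in replicates 1 and 2, and 4 unmarked models held 0 and 2 units. Whether the unmarked 5.8S models are working copies is not known from the files, so these values do not decide it. The missing subunit models keep a germline-specific source and a somatic source from being told apart for the subunits, and no biological explanation was tested.

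Germline-specific models were detected in 6 families that also have unmarked models. A fixed share of reads spilling from every unmarked copy, large enough to give these detected models, was argued against. In 26 of 31 families with at least 10 FPKM on the unmarked side, the germline-specific side was under 1% of it. The median was 0.0322% and the highest 20.9%. A fixed share far below 1% would also leave most families under 1%, so it was not excluded. Reads of a near-identical copy may still contribute in single families. In 5 of the 6 the unmarked side was higher, and the germline-specific side was between 6.61 and 47.9% of it, so that expression and shared reads cannot be told apart without sequence. For NAIP, the unmarked copy of that symbol had 0.339% of the level of the germline-specific one. This argues against spill-over of a minor share of the reads of that copy. Misplacement of nearly all of its reads would give the same values, so it was not excluded. Copies under other symbols were not tested. No biological explanation was tested.

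Of the gene models listed at 0 in one library, 6 had at least 100 units in replicate 2 (among them MOS, IL17RA, CDC37, RIMS2 and DENND6A), and 0 showed the opposite. Sampling of few read pairs was argued against as a matter of counting error only. Among 12985 models with at least 100 units over both libraries, 6 were at 0 in replicate 1, where Poisson sampling of read pairs, at the inferred 4 units per pair, gives 8.8e-05. Pairs copied from few molecules are not independent, so loss of molecules before amplification was not tested. With PM18081 added, 3 of 7 models overlapped a model on the opposite strand (MOS, DENND6A and PM18081), against 28.4% of 12167 models of at least 100 units (exact binomial tail 0.318), so reads of an overlapping gene model on the opposite strand may contribute there and cannot be told apart. The other 4 had no annotated overlap of this kind. A difference between the pools, or a failed estimate in replicate 1, was not tested.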
